A study of Mus musculus with 4 samples.

How the data were processed

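RNA-seq values were analysed for 4 libraries of 32D clone 3 cells, a mouse myeloid progenitor line that grows in interleukin-3. Cells carried either the empty plasmid pEGFP-N1 or the same plasmid with the chemokine receptor CXCR2, with 2 libraries per plasmid. Per the labels, every culture received the CXCR2 ligands CXCL1 and CXCL2, at 50 ng/mL each, for 4 h. Libraries are named here by plasmid and by the number in the submitters' sample code (2 or 3). The labels do not say whether the 2 libraries of a group came from separate transfections or cultures, so p-values measure the spread between these samples, which may be technical.

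The deposited values are treated as FPKM (fragments scaled by gene length and by the depth of the library), made by the authors. The labels do not name the unit, and it was taken from the values. They are decimals that sum to between 298289 and 301512 per library, and low values of a row stand in ratios of small whole numbers, with a step that differs between rows. The submitters' processing notes name HISAT2 2.1.0, Bowtie2 2.2.3 and the mouse build GRCm38, without their roles. The counting tool, the gene annotation and the gene lengths are not given in the sources used here.

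Each file held 30246 rows with Ensembl gene IDs, in 1 order common to all 4 files. Of these IDs, 30160 matched GENCODE release M21 on GRCm38 and 86 did not. Symbols, biotypes and exonic lengths of the listed IDs were taken from that annotation. As reported in the results, the IDs were found not to go with the values beside them. A symbol is therefore used only as the name a row is listed under, and rows are compared between libraries without giving them a gene identity.

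The relative depth of each library and the whole reads behind each row were recovered from the values. A row was accepted when its values gave whole reads within a relative tolerance of 1e-07, which held for 20708 of the 20750 rows above 0 in at least 2 libraries (99.8%). Read numbers are lower bounds, because the recovery does not detect a divisor common to all libraries of a row. For rows with a mean of at least 6 recovered reads, the size of 1 read gave an implied gene length, which was compared by rank with the annotated exonic length. The comparison was tested on simulated data in which rows and IDs were paired correctly and values were made with the annotated exonic lengths. Pairs of libraries were compared over rows with a mean of at least 20 recovered reads, as the median squared difference over that which counting alone would give. The 95% intervals of these ratios come from 200 bootstrap draws of rows and do not cover the spread between cultures.

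The design had been fixed before the data were examined, with a count test for counts and limma for a normalized unit, so limma was used. CXCR2 was compared with vector in all 4 libraries by limma 3.58.1 in R 4.3.3 (empirical Bayes with trend and robust options, two-sided) on log2(FPKM + 1), over rows with a mean of at least 1 FPKM. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low rows. The 29 gene lists fixed in advance were tested with camera at a preset correlation of 0.01 where at least 5 rows were tested, and again with an estimated correlation and with fry. Level percentiles of the lists came from 10000 random lists of the same size. Other steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

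The rule for named genes fixed in advance took Cxcr2, Sap18, the 10 highest and the 10 lowest passing genes, and members of each list. No row passed, and members of lists are not named because the IDs do not go with the values. The examples are instead the 2 rows with the highest and the 2 with the lowest log2 fold change among rows that separated the groups and reached 5 FPKM in one group. This choice, and the housekeeping and top rows quoted by symbol, were made after the values were seen. The alternatives were pseudocount 0.1, no filter, a mean of at least 5, quantile normalization, a fold limit, the replicate number as a block and leaving out each library. A voom fit on the recovered reads was added after seeing the data.

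The limma fit was tested on simulated data for this comparison. In 20 simulations, reads were drawn around the recovered reads, and 200 rows with a mean of at least 2 FPKM were changed by known folds. Each library was drawn independently, without differences shared by many rows of a library. Each row drew its own dispersion around a mean of 0.0015. That mean was estimated within groups, from rows with a mean of at least 200 recovered reads, and was used for all rows. It was the last of 3 tried, after a value set by hand and a trimmed estimate, and was kept because the simulated scatter came closest to the deposited scatter. The median deviation within groups was 0.05 on the log2 scale in both, and the 99th percentile was 0.50 simulated and 0.54 deposited. With a median of 11173 rows tested, 84.2% of rows changed 1.5-fold were recovered, 96.9% of those changed 2-fold, 98.5% of those changed 4-fold and 92.6% of those lowered to 0.5-fold. These shares hold for the simulated setting, with 200 rows changed at once. They are not the power of the test in the deposited libraries, where pairs scattered unequally, from 1.34 to 3.13 times counting noise. Of all calls, 8.26% were false, above the nominal 5%, and with nothing changed a mean of 1.4 rows and at most 5 were called.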

Results

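The series asks what CXCR2 does in myeloid progenitors as they turn into monocytic myeloid-derived suppressor cells. CXCR2 is the chemokine receptor through which CXCL1 and CXCL2 act on myeloid cells. RNA was sequenced from 32D clone 3 cells with the empty plasmid (n = 2 libraries) or with the CXCR2 plasmid (n = 2), all exposed to both ligands for 4 h. The design has no library without ligand, so a difference between plasmids cannot be divided into an effect of the receptor and an effect of its ligands.

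The recovered reads summed to at least 13150839 in vector replicate 2, 15497825 in vector replicate 3, 15152028 in CXCR2 replicate 2 and 15578913 in CXCR2 replicate 3. Relative to vector replicate 3, the depth was 0.853 in vector replicate 2, 0.978 in CXCR2 replicate 2 and 1.003 in CXCR2 replicate 3. Between 11203 and 11260 rows reached 1 FPKM per library.

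The transfected gene was examined first. The row listed under Cxcr2 (ENSMUSG00000026180, GRCm38 chromosome 1, 74153989 to 74161246) was listed at 0 in all 4 libraries, the CXCR2 libraries included. No fold change can be given, and the row does not check the labels, since several genes that every cell uses were listed at or near 0 as well. The row listed under Actb, which encodes the cytoskeletal protein beta-actin, was listed at 0 in 3 libraries and at 0.0609 FPKM in CXCR2 replicate 2. The row listed under Gapdh, a glycolytic enzyme, was at 0 in both vector libraries and at 0.175 and 0.170 FPKM in the CXCR2 libraries. Eef1a1, a translation elongation factor, names a row that did not exceed 0.0688 FPKM. The highest row of the table was listed under Vmn1r45, a vomeronasal pheromone receptor, with 9875 and 8745 FPKM in the vector libraries and 9123 and 8628 FPKM in the CXCR2 libraries. A row listed under Alb, the serum albumin made by liver, held between 11.1 and 13.4 FPKM. Rows listed under genes that blood cells use were not all low: B2m, a subunit of class I histocompatibility molecules, at 13.1 to 13.2 FPKM, the leukocyte surface phosphatase Ptprc at 28.3 to 37.2 FPKM and the cytokine receptor subunit Csf2rb at 14.8 to 17.4 FPKM.

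Levels differed little between most classes of listed gene. The 79 rows listed under cytosolic ribosomal protein genes had a median of 0.0503 FPKM, and 29.1% of them reached 1 FPKM. Over all 30246 rows the median was 0.163 FPKM and 37.1% reached 1 FPKM. Olfactory receptor genes, which are silent in most tissues, had a median of 0.234 FPKM over 601 rows and 37.1% at 1 FPKM or more. Protein-coding genes had a median of 0.164 FPKM, processed pseudogenes 0.200 and long intergenic RNAs 0.153. Of the 29 gene lists, 0 had a median level above the central 95% of random lists of the same size and 4 lay below it, where chance gives 0.725 on each side. The 4 were the lists of monocyte and macrophage markers (percentile 0.41), MYC targets and ribosome biogenesis (1.19), STAT3 pathway and targets (2.34) and glycolysis and hypoxia genes (2.47). Stem and progenitor markers were at percentile 4.03, the ribosomal protein list was at 4.18 and the mitochondrially encoded genes were at 52.8.

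**Figure D1:**
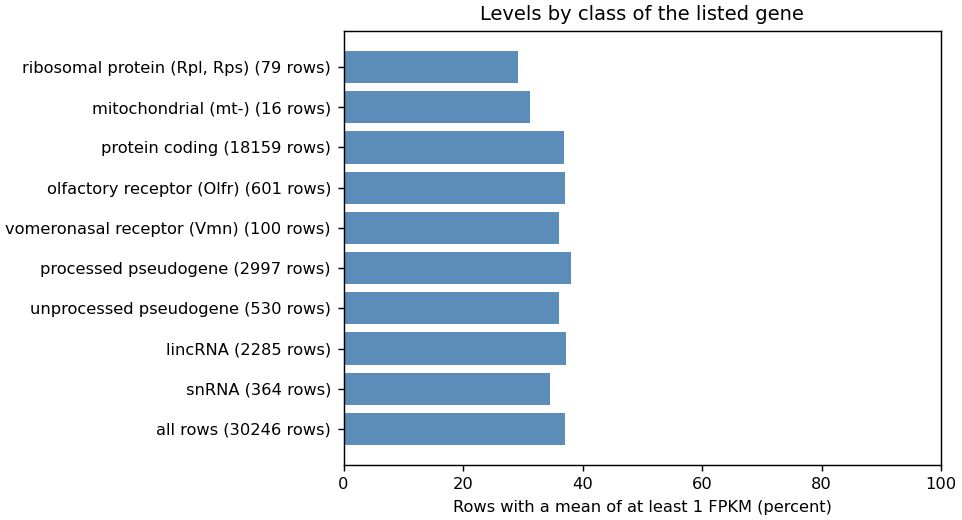
Bars give the percent of rows whose mean over the 4 libraries was at least 1 FPKM, by class of the gene each row is listed under. Ribosomal protein rows reached 29.1% and olfactory receptor rows 37.1%, against 37.1% of all rows.

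The length implied by the size of 1 read was unrelated to the annotated exonic length of the listed gene, with Spearman's rho 0.00751 across 13815 rows. Across 5842 rows listed under genes with 1 annotated transcript it was -0.012. Rows are not independent replicates, and these correlations describe the table. In simulated rows with correctly paired IDs the same calculation gave 0.979 across 13610 rows. The simulated values were made with the same annotated lengths. The 0.979 therefore shows that the calculation recovers lengths, not how closely the authors' own lengths, which are not given, would match. The IDs listed in these files therefore do not name the genes measured, and no statement about a gene or pathway can be drawn from the row names. The shared order of IDs does not by itself show that the values line up across the 4 files. Values of rows with a mean of at least 1 FPKM correlated between libraries at 0.991 to 0.994 (Pearson, log2 scale). CXCR2 and vector values of a row can therefore still be compared.

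**Figure D2:**
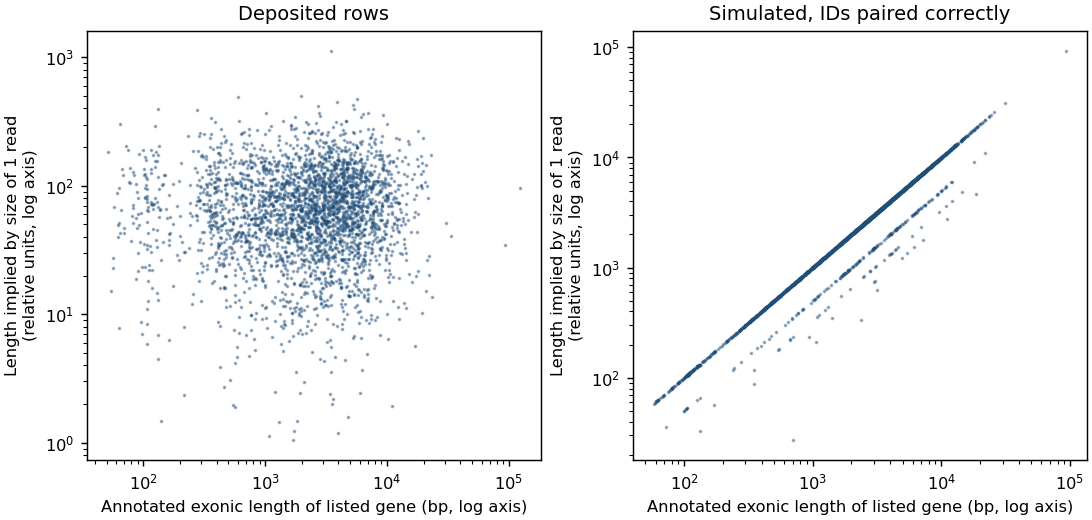
Each point is 1 of 3000 rows drawn at random, with the annotated exonic length of the listed gene (bp, log axis) against the length implied by the size of 1 read (relative units, log axis). The left panel shows deposited rows, where rho over all usable rows was 0.00751, and the right panel shows simulated rows with IDs paired correctly, where it was 0.979.

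In the comparison of CXCR2 with vector, limma called 0 of 11210 rows, 0 higher and 0 lower with CXCR2. At an unadjusted p under 0.05 there were 593 rows (5.29%), and the smallest adjusted p was 0.301. A voom fit on recovered reads also called 0 rows, with 703 at an unadjusted p under 0.05. The median log2 fold change was 0.01 with an SD of 0.14 across rows. The 2 CXCR2 libraries lay on one side of both vector libraries in 4084 rows (36.4%), where chance gives 33.3% for each row. Rows are not independent, and the share was not computed for other splits of the libraries. The gap between the shares therefore cannot be credited to the plasmid. An absolute log2 fold change of at least 1 was seen in 29 rows, 13 higher and 16 lower with CXCR2, and none of these passed the limma test. The count rested on which libraries entered: limma called 14 rows without vector replicate 2, 8 without vector replicate 3, 1 without CXCR2 replicate 2 and 0 without CXCR2 replicate 3.

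Among rows that separated the groups and had a mean of at least 5 FPKM in one group, the 2 highest and the 2 lowest log2 fold changes are given as values, since none passed. Other rows higher with CXCR2 had changes larger in size than the 2 lowest. The row with ID ENSMUSG00000090174, listed under Gm10612 (chromosome 8, 122697860 to 122700160), held 1727 and 1299 FPKM with vector and 4069 and 5853 FPKM with CXCR2. Its means were 1513 ± 303 (SD, n = 2) and 4961 ± 1262 FPKM (SD, n = 2), and its log2 fold change was 1.70 with a standard error of 0.21 and a limma adjusted p of 0.421. The row ENSMUSG00000097681, listed under Gm26643 (chromosome 4, 43030999 to 43032482), held 41.6 and 48.0 FPKM with vector and 118 and 219 FPKM with CXCR2, with a log2 fold change of 1.82, a standard error of 0.28 and a limma adjusted p of 0.618. The row ENSMUSG00000097429, listed under Gm26520 (chromosome 12, 3343816 to 3357153), held 8.25 and 3.73 FPKM with vector and 2.12 and 2.89 FPKM with CXCR2, with a log2 fold change of -0.93, a standard error of 0.32 and a limma adjusted p of 0.853. The size of that difference depended on the vector libraries, as it was -0.44 without vector replicate 2, the library with 8.25 FPKM, and -1.41 without vector replicate 3. The row ENSMUSG00000031431, listed under Tsc22d3 (chromosome X, 140539528 to 140600659), held 6.57 and 6.31 FPKM with vector and 2.87 and 3.49 FPKM with CXCR2, with a log2 fold change of -0.84, a standard error of 0.09 and a limma adjusted p of 0.301. Coordinates are those of the listed IDs on GRCm38. The largest log2 fold change among such rows with a symbol was 1.82. None of them therefore rose from near 0 with vector to 5 FPKM or more in both CXCR2 libraries. The transfected gene would do so only if vector cells lacked it and the annotation counted the plasmid's transcript. Neither is known, so the absence of such a row does not decide whether CXCR2 was expressed. The row listed under Sap18, a gene named in advance, held 341 and 338 FPKM with vector and 328 and 330 FPKM with CXCR2.

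**Figure D3:**
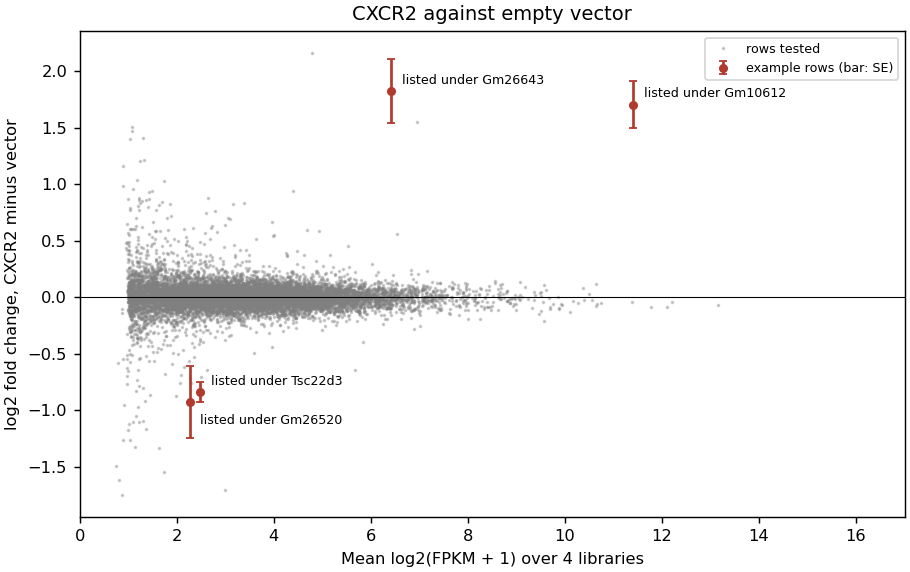
Each grey point is 1 of 11210 rows, with its mean log2(FPKM + 1) over the 4 libraries against its log2 fold change, CXCR2 minus vector. Red points are the 4 example rows with bars of 1 standard error, from -0.93 to 1.82, and none of the rows passed the limma test.

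Of the 29 fixed gene lists, 28 had at least 5 tested rows, and camera called 0 of them, with 0 at an unadjusted p under 0.05. The smallest adjusted p was 0.872 with the preset correlation, 0.926 with an estimated correlation and 0.970 with fry. Over all rows tested 0 members passed, and adjusted over the list alone 4 members of 3 lists passed limma. Because the IDs do not go with the values, the result cannot be read as one on the pathways the lists are named for.

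The scatter between libraries did not order all pairs by plasmid. Over 11676 rows the median squared difference was 1.74 times counting noise between the vector libraries (95% bootstrap interval 1.67 to 1.80) and 2.11 times between the CXCR2 libraries (2.02 to 2.21). Vector replicate 3 and CXCR2 replicate 2 differed least, at 1.34 times, and vector replicate 2 and CXCR2 replicate 3 most, at 3.13 times. These sizes depended on the reads per row: over rows with a mean of 20 to 500 recovered reads the most distant pair was at 1.79 times, and the lowest ratios were 1.22 for vector replicate 2 with CXCR2 replicate 2 and 1.23 for vector replicate 3 with CXCR2 replicate 2. Over all 11676 rows, vector replicate 2 and CXCR2 replicate 2 were at 1.64, and vector replicate 3 and CXCR2 replicate 3 at 2.25. In these same rows CXCR2 replicate 3 had its lowest ratio with its group mate, though the interval overlaps that with vector replicate 3. Vector replicate 2 had its lowest ratio with CXCR2 replicate 2, though the interval overlaps that with its group mate. Each pair differed by more than counting noise, so no library was a second deposit of another.

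**Figure D4:**
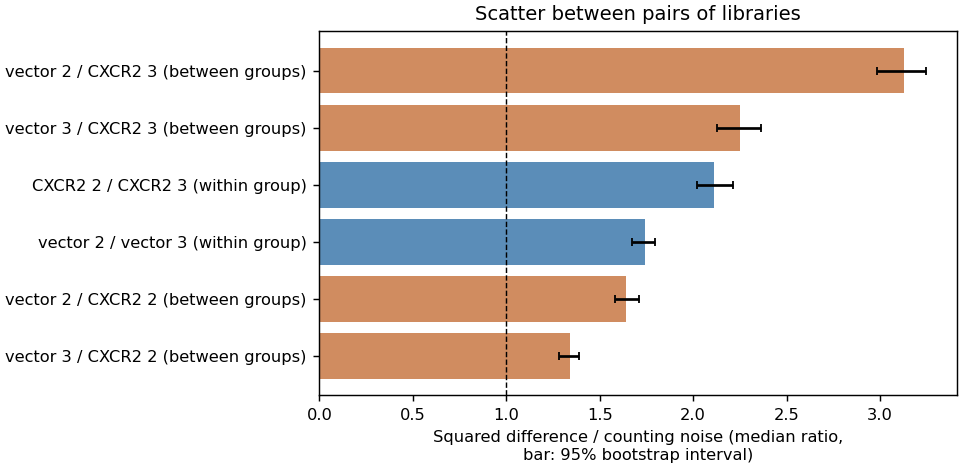
Bars give the median squared difference between libraries over that which counting alone gives, for the 6 pairs, with 95% bootstrap intervals over rows. Blue bars are pairs within a group and orange bars pairs between groups, and the dashed line at 1 is counting noise alone.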

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

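The count of 0 rows from limma stayed at 0 with pseudocount 0.1 (592 at an unadjusted p under 0.05), without a filter (1003), with a mean of at least 5 (428), with quantile normalization (595) and with a fold limit. A voom fit on recovered reads, chosen after seeing the data, also gave 0 (703). Leaving out 1 library gave from 0 to 14 rows called, from 0 to 10 higher and from 0 to 4 lower. The count was 14 without vector replicate 2 (10 higher, 4 lower), 8 without vector replicate 3 (7 higher, 1 lower), 1 without CXCR2 replicate 2 (0 higher, 1 lower) and 0 without CXCR2 replicate 3. In these fits the lone library of a group is assumed to vary like the other group, and the cause of the difference was not tested. With the replicate block 0 rows were called (1102 unadjusted), 0 higher and 0 lower. The labels do not say what the number means, and the deviations of same-numbered libraries from the group means correlated at 0.0805 across rows, so whether the numbers pair libraries is open. The main fit had been fixed without the block. The count of gene lists called was 0 under each setting run for it, the replicate block and left-out libraries included. The 4 example rows kept their sign and stayed short of the threshold, but the row listed under Gm26520 moved from -0.93 to -0.44 without vector replicate 2 and to -1.41 without vector replicate 3. This row and that listed under Tsc22d3 have no value at a mean of at least 5, which they do not reach. Tests that need deposited counts were not run, because the unit is FPKM. The row listed under Cxcr2 is at 0 throughout and gives no fold change under any setting.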

Other observations

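The 4 tests on row IDs below were chosen after the housekeeping rows had been seen, while the 2 on the comparison of plasmids, called rows by split and the depth of vector replicate 2, were written before their results. The depth test was reworded for a time after its result had been seen, and is given here as first written. The counts of rows at an unadjusted p in other splits were added after the data were seen. Housekeeping genes such as Actb and Gapdh were listed at or near 0, and a vomeronasal receptor gene was listed highest. The explanation reached in the results is that the row IDs do not belong to the values beside them. It called for no relation of implied with annotated length, and the correlation was 0.00751. Silence of the listed genes in these cells would leave lengths and IDs paired, and the correlation of -0.012 among genes with 1 transcript argues against that. A slip of the ID column by a fixed number of rows is argued against by the highest correlation over 30246 shifts, 0.0372, where a displaced column in simulated rows was found at 0.971. Sorting the IDs gave 0.0136, so a sort of that column alone does not restore the pairing.

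Other orders of the whole ID column gave no pairing either. The correlation was -0.00903 with the IDs sorted in reverse, 0.00778 with symbols sorted and -0.00263 with the ID column reversed. Shifts within windows of rows were also looked at, but no result was kept that can be given here, and no re-pairing is used. Both columns keep some order: neighbouring rows correlated at 0.115 in mean log2 level, against at most 0.0177 in 1000 shuffles. In 41.0% of neighbouring rows the IDs differed only in the last digit, against 0.00331% in shuffled rows.

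The 3 ways of splitting the 4 libraries into pairs are too few for a share under 0.05. Limma called 0 rows in the real split and at most 0 in the other splits, so all 3 tie. At an unadjusted p under 0.05 the real split gave 593 rows, the split that puts same-numbered libraries together gave 653 and the crossed split gave 275. Whether the lower depth of vector replicate 2 (0.853) shapes the comparison stays open. The smaller noise ratio of vector replicate 3 with a CXCR2 library was 1.34, below the 2.11 of the CXCR2 pair, which does not exclude it. The larger was 2.25, above 2.11 with overlapping intervals, where the explanation had called for neither to exceed 2.11. The pairs with vector replicate 2 were not the 3 most scattered, which the explanation had also called for, as 1.74 and 1.64 lie below 2.25. The noise ratio already allows for relative depth, so it cannot decide the question.

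The first principal component, with 43.8% of the variance, placed vector replicate 2 at -11.5 and CXCR2 replicate 3 at 11.8, with vector replicate 3 at -0.355 and CXCR2 replicate 2 at 0.0236 between them. On it both vector libraries lay below both CXCR2 libraries, by the narrow gap from -0.355 to 0.0236, and replicate 3 lay above replicate 2 within each group.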
